A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

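Expression was profiled in Saccharomyces cerevisiae of the sigma 1278b background on the Affymetrix Yeast Genome S98 array, 1 sample per array. Per the labels' protocols, each gene was deleted with a drug-resistance cassette, haploid mutants were mated, and diploids were selected by growth without tryptophan and leucine. Diploid cultures were grown at 30 °C in rich medium to an optical density of 0.6, washed, and moved to a low-ammonium medium with 50 µM ammonium sulfate and 2% glucose. Poly(A) RNA was purified with a kit, reverse transcribed, and transcribed in vitro into biotin-labelled RNA. The time spent in the low-ammonium medium is not given in the sources used here.

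The deposited values are on a log2 scale, as judged from their range, with array maxima of 13.9 to 14.1, because the log base is not given in the sources used here. RMA and GCRMA, methods that correct background, normalize arrays and summarise probes into probe sets, are both named per the submitters' processing notes, with no version. Which of them made the values, and whether the 6 arrays were normalized together, is not given in the sources used here. Both methods pull arrays toward a common distribution, so a shift in most genes would be partly removed and partly passed to other genes. The values were used as deposited.

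The array holds 9335 probe sets, of which 60 are controls. Gene symbols came from GEO's platform annotation. It lists 1 gene for 6504 probe sets, several for 328 and none for 2443. The 6832 probe sets with a listed gene were tested, and no gene was named from a probe set with several. The 6504 probe sets with 1 gene stand for 5656 genes and were all matched to a locus tag in a RefSeq gene table of assembly R64, used only for names, neighbouring genes and coding length, introns included. The build behind the array is not given in the sources used here, so no coordinates are printed. Gene lists used the brightest probe set of a gene, and the text says where other probe sets of a named gene above background had another call, without naming each of them. The position of probe sets within genes is not given in the sources used here, except for control genes whose names carry 5′, middle or 3′.

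Groups were taken from the genotype label, with 4 arrays of flo8Δ and 2 of mss11Δ. The test was limma's lmFit and eBayes without covariates, with Benjamini-Hochberg adjustment over the 6832 probe sets and an adjusted p under 0.05. The series text names SAM, two-class and unpaired, at a false discovery rate of 0. limma took its place because it pools the spread over genes, and a SAM written for this work over all 15 label assignments was an alternative. A probe set counted as below background in a group where every array lay below 3.49, the highest value of 28 negative control probe sets on any array. That level was made common to all arrays after the data were seen, because FLO8 on 3 of the 4 flo8Δ arrays lay above that array's own highest negative control. A fold against such a group is a bound. It sets the bright group's mean against the dim group's mean after each dim value is raised to the highest negative control where that is the higher.

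Gene lists numbered 39, and 38 had at least 3 measured genes. They covered flocculins, filamentous growth regulators, Tec1 and Ste12 targets, nitrogen catabolite repression, autophagy, amino acid biosynthesis, sulfate and methionine, ribosomal proteins, ribosome biogenesis, environmental stress, chaperones, glycolysis, hexose transport, the TCA cycle, the respiratory chain, the glyoxylate cycle, beta-oxidation, ergosterol, a-specific, alpha-specific, haploid-specific, pheromone-induced and meiotic genes, G1/S, G2/M, daughter separation, histones, cell wall, anaerobic cell wall, seripauperins, COS genes, Y prime helicases, phosphate, iron, zinc, thiamine and pyridoxine, proteasome, strain markers, and the neighbours of the deleted genes. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 38 lists. List medians were also set against 10000 random lists matched on brightness in 20 bins.

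Samples, lists, tests and most alternatives were fixed before the data were examined, as was the rule for named genes. The rule took FLO8, MSS11 and FLO11, the 12 genes with the largest difference in each direction among calls whose groups do not overlap, up to 4 members with the smallest p per list, the neighbours of the deleted genes, and the strain markers. Named after their values were seen were the other probe sets of these genes, CPA1, the genes whose probe sets all had the same call, SUL1, MET28, MET6, MET10, MEP2, GAP1, TDH1, CIT3, IDP1, FUS3, IME1, MF(ALPHA)1, MF(ALPHA)2 and the genes that open the other observations.

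Genes with several probe sets were counted without probe sets below background in both groups. The alternatives were quantile normalization, median centring, a filter on dim probe sets, eBayes with trend and robust fitting, array weights, the replicate number as a block, arrays 1 and 2 alone, each array left out in turn, a 2-fold threshold, SAM, all probe sets of the table, and 1 probe set per gene. Those added after seeing the data were centring on the probe sets brighter than the median, a filter on background, the ACT1 control difference as a covariate, leaving out flo8Δ array 3 with mss11Δ array 2, and the mean of all probe sets of a gene. The fit was tested on simulated data with 200 changed probe sets among 6832 in 4 and 2 arrays. It recovered 54.4% of changes of 0.5, 93.9% of changes of 1 and 100% of changes of 2 on the log2 scale, with 8 false calls among 173. In the simulated lists the 1 shifted list was found and 0 others were called. Simulated genes varied independently, so this does not test list calls among genes that vary together. In the data the estimated correlation reached 0.79, for ribosomal proteins. The changed probe sets were drawn from those brighter than the median, and in the data far more, 2760, were called. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. Probe sets without a listed gene were left out of the named comparison because no table names them.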

Results

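Gene expression was measured on 6 oligonucleotide arrays of budding yeast, Saccharomyces cerevisiae, in the sigma 1278b background, whose diploids can grow as pseudohyphal filaments on little nitrogen. The strains were homozygous diploids that lacked FLO8 (flo8Δ, 4 arrays) or MSS11 (mss11Δ, 2 arrays), and their RNA was taken after a move from rich medium to a medium low in ammonium. FLO8 and MSS11 encode transcription factors that act together at the promoter of the flocculin gene FLO11. The comparison asks which transcripts differed between the deletions under nitrogen stress. The wild type is not analysed here, so a transcript that was higher in flo8Δ was equally lower in mss11Δ. Each difference below is the log2 level in flo8Δ minus that in mss11Δ, and it is positive where flo8Δ was higher. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

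The deposited log2 values had medians of 8.12, 8.13, 8.11 and 8.11 on flo8Δ arrays 1 to 4 and of 8.17 and 8.16 on mss11Δ arrays 1 and 2. Across probe sets, arrays of flo8Δ correlated with each other at r = 0.986 to 0.998 (6 pairs) and those of mss11Δ at 0.995, against 0.915 to 0.955 (8 pairs) between the groups. No pair of arrays held identical values. The control probe sets for actin (ACT1), which lie toward the 5′ and the 3′ end of its mRNA, differed between the groups. The 5′ minus 3′ difference was -0.48 ± 0.11 on flo8Δ arrays (SD, n = 4) and -3.71 ± 1.77 on mss11Δ arrays (SD, n = 2), with -2.46 on array 1 and -4.97 on array 2. For SRB4 it was -1.78 ± 0.41 against -5.07 ± 0.07, and for SPT15 -0.68 ± 0.10 against -1.10 ± 0.59. Signal far from the 3′ end of ACT1 and SRB4 was thus lower on both mss11Δ arrays. For SPT15 it was lower on array 2, at -1.52, while array 1, at -0.69, lay among the flo8Δ arrays, at -0.82 to -0.58. Every difference between the genotypes described here was measured across the shift in ACT1 and SRB4.

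Each deleted gene was low in its own deletion strain, and FLO11 did not differ past the threshold. In sulfate assimilation and methionine synthesis 17 of 21 measured genes were lower in flo8Δ, among them MET32 at a difference of -2.00. Of 16 genes of glycolysis and fermentation, 7 were higher in flo8Δ, among them ENO1 by 0.82. These counts fell to 10 and 3 without mss11Δ array 1 and to 8 and 3 without mss11Δ array 2. In the lists for G1/S, G2/M and meiosis, 15 of 24, 8 of 15 and 16 of 38 genes were lower, and 1, 0 and 1 higher. Without mss11Δ array 1 the lower genes were 9, 4 and 12, and without array 2 they were 5 in each list. The differences of at least 2-fold went mostly the other way, with 486 probe sets higher in flo8Δ and 32 lower. With the dimmest probe sets left out, so that 4554 were tested, these counts were 112 and 20, and after quantile normalization 442 and 75. In many of the genes behind the higher ones another probe set was not called higher.

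FLO8 (YER109C) read 3.32 ± 0.03 in flo8Δ (SD, n = 4) and 8.23 ± 0.03 in mss11Δ (SD, n = 2). The difference was -4.90 ± 0.05 (SE, adjusted p = 8.15e-07), or at least 26.6-fold lower, because all 4 flo8Δ arrays lay below the brightest negative control, at 3.49. A second probe set of FLO8 lay below that level in both strains, at 2.73 and 2.85, and shows nothing about the deletion. MSS11 (YMR164C) read 6.55 ± 0.25 in flo8Δ and 3.23 ± 0.40 in mss11Δ, a difference of 3.32 ± 0.21 (SE, adjusted p = 0.000401). The mss11Δ values were 2.95 and 3.51, so 1 of the 2 lay below background and the size of the difference is uncertain. MSS11 has 1 probe set, and 486 probe sets in all were called at least 2-fold higher in flo8Δ, against 32 lower. The MSS11 value therefore checks the genotype label less firmly than that of FLO8, which went the other way. FLO11 (YIR019C), the flocculin needed for filaments and adhesion, read 6.66 ± 0.12 and 6.85 ± 0.001, a difference of -0.19 ± 0.09 that was not past the threshold (adjusted p = 0.127). It passed after quantile normalization, at -0.45 (adjusted p = 0.0249), and without flo8Δ array 1, at -0.24 (adjusted p = 0.0428), within a range of 0.0249 to 0.727 over all alternatives. The genes on either side of the deletions also differed. PAH1, next to MSS11, was higher in flo8Δ by 0.40, and INP2 on its other side was lower, at -0.48. GLE2 and KAP123, which flank FLO8, were lower at -0.46 and -0.45. Adjusted over the list alone, 1 of these 4 neighbours was higher and 3 lower, and the lower ones over all genes fell to 1 without either mss11Δ array or without flo8Δ array 2 or 4. As a group they had a median of -0.46 and did not differ from other genes (camera adjusted p = 0.845).

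**Figure D1:**
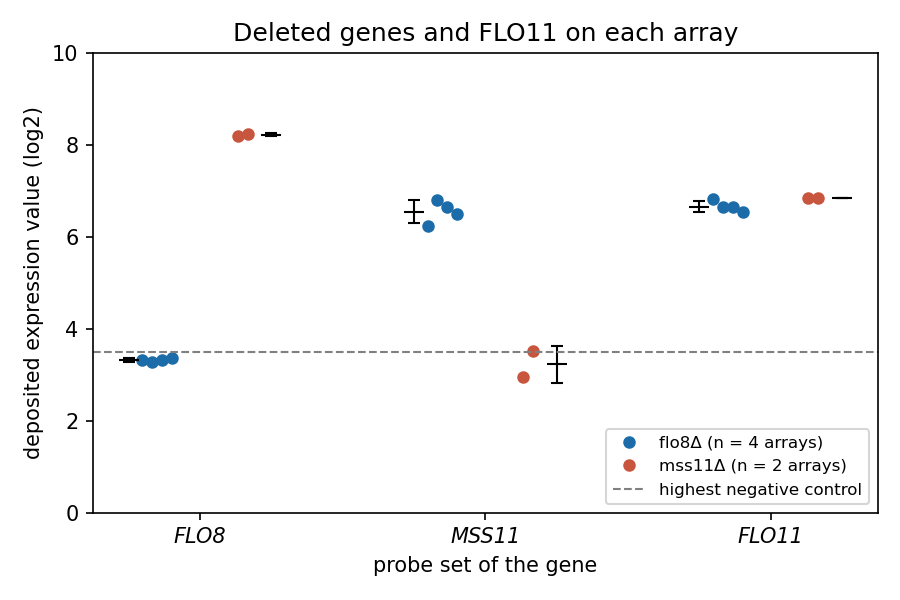
Deposited log2 expression values of FLO8, MSS11 and FLO11 on each array of flo8Δ (n = 4) and mss11Δ (n = 2), with points for arrays and a dashed line at the brightest negative control, 3.49. FLO8 lies below the line on all 4 flo8Δ arrays and at 8.23 on average in mss11Δ, MSS11 is lower in mss11Δ, and the FLO11 means are 6.66 and 6.85.

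Among 6832 named probe sets, 2760 (40.4%) differed past an adjusted p of 0.05 in limma, 983 higher and 1777 lower in flo8Δ. In each of the 2760, all 4 flo8Δ arrays lay on one side of both mss11Δ arrays. That held for 4346 probe sets (63.6%) in all, where chance gives 13.3%. The median difference over named probe sets was -0.11. Centring each array on the probe sets brighter than its median moved that median to -0.007 and the share of higher calls from 35.6% to 57.3%, and centring on the array median moved the share to 46.7%. Differences under 2-fold were mostly lower in flo8Δ, 1745 against 497, and the lower ones had a median of -0.39. In 120 of the 486 probe sets called 2-fold higher mss11Δ lay below background, and in 17 of these the bound was under 2-fold. With 1 probe set per gene, the brightest, 619 of 5656 genes were higher and 1781 lower, and by at least 2-fold 176 were higher and 31 lower. Without mss11Δ array 2 the count was 1274, without mss11Δ array 1 it was 1580, and with the ACT1 control difference as a covariate it was 88.

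The largest higher value belonged to FAS2, the alpha subunit of fatty acid synthase, where one probe set read 11.29 ± 0.21 in flo8Δ (SD, n = 4) and 3.24 ± 0.26 in mss11Δ (SD, n = 2), at least 222-fold higher (adjusted p = 1.12e-05). The brightest probe set of FAS2 read 12.51 and 11.64, a difference of 0.87 that was not past the threshold (adjusted p = 0.0519), and the next brightest 11.80 and 11.88, a difference of -0.07 (adjusted p = 0.587). The 4 FAS2 probe sets not yet named that lay above background in flo8Δ were also higher. FKS1, a catalytic subunit of the glucan synthase that builds the cell wall, had a probe set at least 71.7-fold higher and a brighter one that differed by -0.14 (adjusted p = 0.0617). Such unlike probe sets also occurred in 6 other genes among the 12 with the largest higher values. GSC2, a glucan synthase of spore walls, differed by 7.14 in one probe set and 0.12 in another. BDS1, a sulfatase, had a probe set at least 48.2-fold higher and another that differed by 0.17. VMA1, a subunit of the vacuolar proton pump, differed by 6.25 and -0.13, and the mevalonate kinase gene ERG12 by 6.04 and -0.03. The kinetochore gene SPC105 had a probe set at least 32.4-fold higher and another that was lower, at -0.29 (adjusted p = 0.0247). FAS1, the beta subunit of fatty acid synthase, was higher by 6.55 in one probe set, by 0.93 in its brightest (adjusted p = 0.0242) and also in 4 others, and differed by -0.10 in a further one. Further probe sets were also higher, 4 for FKS1, 5 for GSC2, 2 for BDS1, and 1 each for ERG12 and SPC105. TEF4, a translation elongation factor subunit, was higher in both of its probe sets, by 6.02 and 0.69. The 6.02 of TEF4 and the 6.04 of ERG12 are of uncertain size, because mss11Δ array 2 lay below background in both. PHO4, the transcription factor of the phosphate response, and SGF29, a subunit of histone acetyltransferase complexes, have 1 probe set each and were at least 32.3-fold and 41.5-fold higher. A single probe set cannot tell a loss of signal on the mss11Δ arrays from a difference in transcript level. Of 13 measured genes in the phosphate list, 2 were higher and 2 lower in flo8Δ. YOR302W, the reading frame in the leader of the CPA1 mRNA, differed by 5.97 ± 0.18 (SE, adjusted p = 5.10e-05), whereas CPA1 itself read 12.04 in both strains (adjusted p = 0.974). The leader is the 5′ part of that mRNA, and the 5′ controls of ACT1 and SRB4 were also low on mss11Δ arrays. A loss of 5′ signal may thus account for the YOR302W value, which does not show a difference in the CPA1 transcript.

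**Figure D2:**
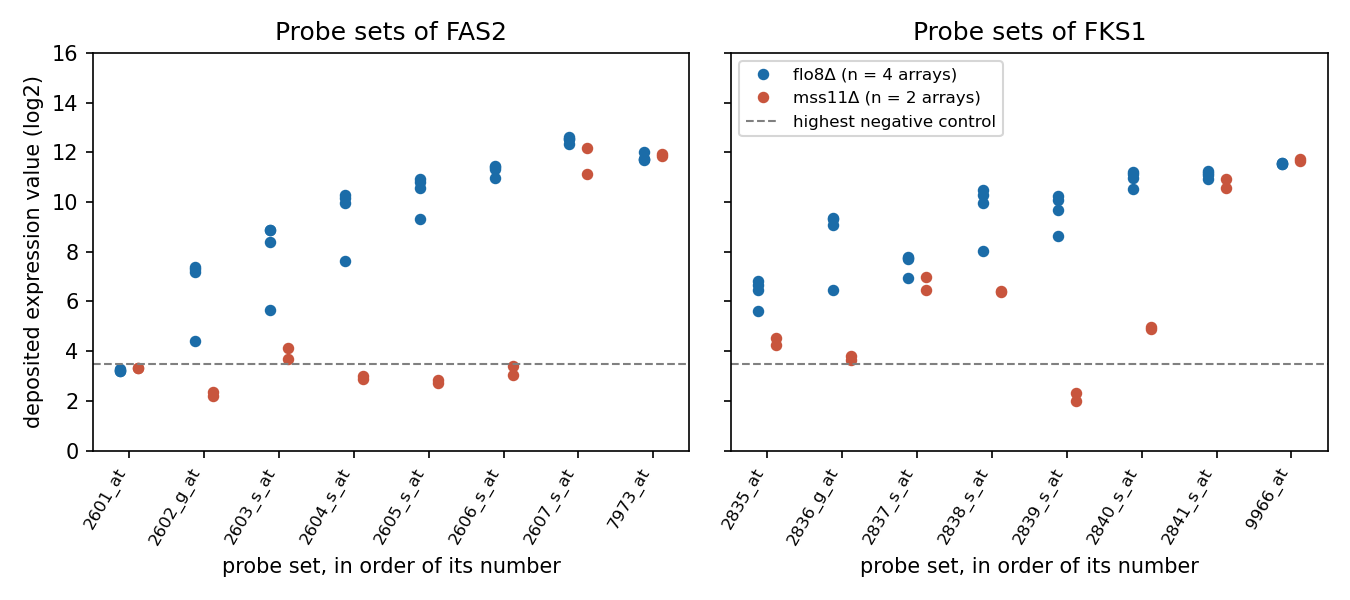
Deposited log2 expression values of each probe set of FAS2 (left) and FKS1 (right) on every array of flo8Δ (n = 4) and mss11Δ (n = 2), in order of probe set number, with a dashed line at the brightest negative control, 3.49. One FAS2 probe set is at least 222-fold higher in flo8Δ and the one at the right end differs by -0.07, and 1 probe set of FKS1 is at least 71.7-fold higher and another differs by -0.14.

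Of 296 genes with several probe sets above background in either strain, 29 had the same call in all of them, 19 higher and 10 lower, and 52 had both higher and lower calls. A 2-fold higher probe set occurred in 137 of the 296 genes, and in 16 of these all probe sets were higher. In 8 genes every probe set was higher by at least 2-fold. ATG15, the lipase that breaks down autophagic bodies in the vacuole, was higher by at least 4.39 in each of 3 probe sets. COX1, the mitochondrial gene for a subunit of cytochrome c oxidase, was higher by at least 2.34 in 3, and MPS3, a gene of the spindle pole body and nuclear envelope, by at least 1.23 in 3. The others were the ribosomal RNA gene RDN5-1, COS10, COS7, YAR009C and YLR415C. For YLR415C mss11Δ lay below background, so that its bounds were only 1.33-fold and 1.83-fold. The 25S rRNA control read 5.82 to 10.2 on flo8Δ arrays and 4.95 and 5.67 on mss11Δ arrays. On flo8Δ array 3, where it was highest, the RDN5-1 probe sets lay above the other flo8Δ arrays by 0.89 and 1.17. For 2 COX1 probe sets this was 0.28 and 0.79. Carried-over RNA without poly(A) was not tested for these genes alone. Among the 10 lower genes were RPS22B, a ribosomal protein, with a difference of -0.56 or lower in 3 probe sets, and SUC2, invertase, at -0.37 or lower in 2 probe sets.

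MET32, a transcription factor of the sulfur pathway, had the largest lower value after FLO8. It read 7.77 ± 0.36 in flo8Δ (SD, n = 4) and 9.76 ± 0.21 in mss11Δ (SD, n = 2), a difference of -2.00 ± 0.24 (SE, adjusted p = 0.00268). SUL2, a sulfate permease, differed by -1.60, MET2, which acetylates homoserine, by -1.34, and YCT1, a cysteine transporter, by -1.43. OPT1, which imports glutathione and peptides, and DUG3, which helps to degrade glutathione, both differed by -1.57. GPH1, glycogen phosphorylase, differed by -1.44, GPP2, which makes glycerol, by -1.41, PMU1 by -1.33 and YKL068W-A by -1.57. ALG3, a mannosyltransferase of N-glycosylation, had probe sets at -1.92, -0.49 and -0.07, the last not past the threshold (adjusted p = 0.627). With either mss11Δ array left out, SUL2, MET2, YCT1, OPT1, GPP2, PMU1 and YKL068W-A were no longer past the threshold, with adjusted p from 0.0633 (PMU1) to 0.126 (MET2). SUL2, GPP2 and MET2 also missed it without flo8Δ array 2 (adjusted p = 0.0602, 0.0538 and 0.0633).

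In the sulfate and methionine list, 17 of 21 genes were lower in flo8Δ and 1 higher, and adjusted over the list alone 19 were lower and 1 higher. The count of 17 fell to 12 without flo8Δ array 2, to 10 without mss11Δ array 1 and to 8 without mss11Δ array 2. With the ACT1 control difference as a covariate 1 gene passed, as errors widened (for MET32 from 0.24 to 0.59), while the list median was -0.73 and the list passed camera (adjusted p = 0.00126). In the fit without it the list median was -0.69 and brightness-matched random lists had a median of -0.10, above the observed value in each of 10000 draws. STR3, which converts cystathionine to homocysteine, differed by -1.32 ± 0.09 (SE, adjusted p = 0.000452). MET5, a subunit of sulfite reductase, differed by -0.99 and MET14, adenylylsulfate kinase, by -0.89. The exception was SUL1, the other sulfate permease, higher by 0.86 ± 0.24 (SE, adjusted p = 0.0334), which did not pass without flo8Δ array 1, 2 or 4 or mss11Δ array 2. MET28, at -1.89 (adjusted p = 0.0623), MET6 at -0.28 and MET10 at -0.09 were not past the threshold. The median level of the list was 10.55, 10.56, 10.69 and 10.59 on flo8Δ arrays and 11.29 and 11.13 on mss11Δ arrays, while the ACT1 control difference was -0.48 and -3.71. The list differed from other genes in camera with a preset correlation (adjusted p = 0.00222), and not with an estimated one (adjusted p = 0.522 with an estimated correlation).

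**Figure D3:**
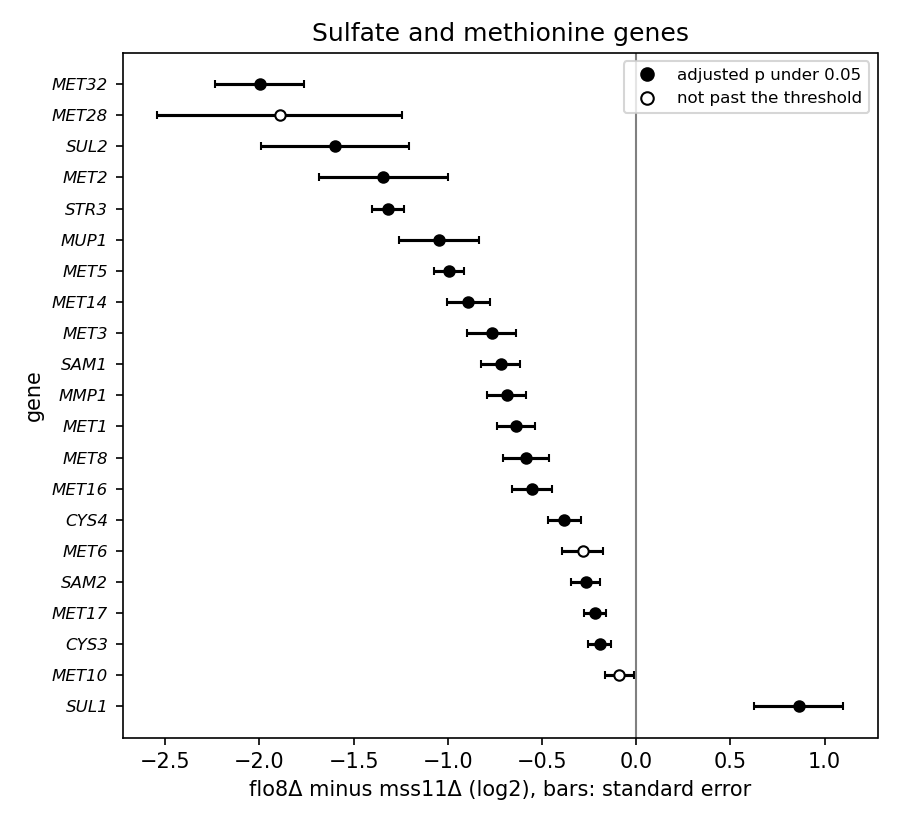
Log2 difference between flo8Δ (n = 4 arrays) and mss11Δ (n = 2 arrays) for the 21 measured genes of sulfate assimilation and methionine synthesis, with bars for the standard error and filled points where the adjusted p was under 0.05. MET32 lies lowest at -2.00 and SUL1 highest at 0.86, with 17 filled points below 0.

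The regulators of filamentous growth went both ways. Of 32 measured, 6 were higher in flo8Δ and 2 lower, with the same counts adjusted over the list alone. The lower ones numbered 4 without flo8Δ array 3 and 1 without any other single array. TPK2 and TPK3, catalytic subunits of protein kinase A, were higher by 0.39 and 0.52, and DIG1, an inhibitor of the filamentation factor Ste12, by 0.38. HMS1, a pseudohyphal growth factor, was lower at -0.45. The list median was 0.03 and turned negative without mss11Δ array 2, and camera placed it higher (adjusted p = 0.0114, and adjusted p = 0.296 with an estimated correlation). It passed in 15 of 17 refits, but not without flo8Δ array 3 and mss11Δ array 2 together (adjusted p = 0.0622, within a range of 0.00634 to 0.347 over the alternatives). Of 8 targets of Tec1 and Ste12, the polygalacturonase gene PGU1 was lower at -0.85 and the cyclin gene CLN1 at -0.65, and none was higher, also over the list alone. That list had a median of -0.06, which turned positive with arrays centred on the brighter probe sets (camera adjusted p = 0.971). None of 4 flocculin genes passed in its brightest probe set, also over the list alone, with FLO10 at -0.22, FLO5 at 0.22, and FLO1 below background in both strains (list median -0.14, camera adjusted p = 0.845). Among the other probe sets, 3 of FLO10 were higher, at 3.41, 2.05 and 1.03, and 1 was lower, at -0.23. Another of FLO5 was also called higher, by at least 1.72-fold. After quantile normalization 2 flocculin genes were lower, and 1 without flo8Δ array 1.

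Of 28 genes under nitrogen catabolite repression, 4 were higher in flo8Δ and 3 lower, and likewise over the list alone. Their median levels were 11.44 in flo8Δ and 11.67 in mss11Δ. CAR1, arginase, was higher by 1.69 ± 0.14 (SE, adjusted p = 0.000896), GAT1 by 0.34 and DAL1 by 0.41, and ATG14 was lower at -0.47. The ammonium permease gene MEP2 and the general amino acid permease gene GAP1 differed by 0.05 and 0.04 and were not past the threshold. The list median was -0.03, against a mean of 0.005 and a higher direction in camera (adjusted p = 0.133), and it was positive with either centring of the arrays. In autophagy, 4 of 18 genes were higher and 5 lower (5 and 6 adjusted over the list alone). ATG15 was at least 37.0-fold higher, and ATG16, ATG13 and ATG8 were higher by 1.16, 0.76 and 0.49. The autophagy median of -0.11 had the opposite sign to its mean of 0.29 and its direction in camera (camera adjusted p = 0.181). Of 40 genes of amino acid synthesis, 4 were higher and none lower, also over the list alone. LYS20, which begins lysine synthesis, was higher by 0.89, ARO2 by 0.55, ARO3 by 0.44 and THR1 by 0.37. The median of that list was 0.10 (camera adjusted p = 0.000282, and adjusted p = 0.560 with an estimated correlation), and it turned to -0.14 with the ACT1 control difference as a covariate (adjusted p = 0.920). Without flo8Δ array 3 the higher genes of amino acid synthesis numbered 8 and the lower genes under nitrogen catabolite repression 6, the latter 1 without either mss11Δ array. The lower autophagy genes numbered 3 without flo8Δ array 2 or 4 and 2 without either mss11Δ array.

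In 3 lists of energy metabolism more genes passed as higher than as lower in flo8Δ. In glycolysis and fermentation 7 of 16 genes were higher and 1 lower, and 9 and 1 adjusted over the list alone. ENO1, enolase, was higher by 0.82, PGI1 by 0.43, PGK1 by 0.39 and the alcohol dehydrogenase gene ADH1 by 0.29, and TDH1 was the lower one, at -0.70. The median of 0.22 passed camera (adjusted p = 0.000289, and adjusted p = 0.296 with an estimated correlation). In the tricarboxylic acid cycle 5 of 17 genes were higher and 2 lower (5 and 3 over the list alone). MDH1, mitochondrial malate dehydrogenase, was higher by 0.98, LPD1 by 0.52, SDH2 by 0.51 and KGD1 by 0.37, while IDP1 was lower at -0.23 and CIT3, below background in flo8Δ, by at least 1.17-fold. The cycle's median was 0.15 (camera adjusted p = 0.0114, and adjusted p = 0.296 with an estimated correlation). In the respiratory chain and ATP synthase 7 of 33 genes were higher and 2 lower (6 and 2 over the list alone), led by RIP1 at 0.92, QCR2 at 0.51, ATP1 at 0.47 and ATP16 at 0.36. That median was 0.02 (camera adjusted p = 0.00785, and adjusted p = 0.308 with an estimated correlation), and it lay just under 0 without mss11Δ array 1. The 7 higher genes of glycolysis and fermentation fell to 4 without flo8Δ array 2 or 4 and to 3 without either mss11Δ array, and the 5 of the tricarboxylic acid cycle to 3 without mss11Δ array 2. With arrays centred on the brighter probe sets 9 genes of the cycle and 12 of the respiratory chain were higher. Across these groups the ACT1 control difference was -0.48 in flo8Δ and -3.71 in mss11Δ.

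The lists for hexose transport, the glyoxylate cycle, beta-oxidation and ergosterol synthesis did not pass camera. HXT2, a glucose transporter, was higher by 1.15 and HXT6 by 0.26, and STL1 and HXT10 were lower at -0.16 each, among 14 hexose transport genes (1 higher and 0 lower over the list alone). Of these 14 genes, 2 lay below background in both strains, where the signal is not usable. The hexose transport median of -0.01 had the opposite sign to its mean of 0.11 and its direction in camera and turned positive with either centring (camera adjusted p = 0.160). Without the dim probe sets the list passed, at 0.19 (adjusted p = 0.00572, within a range of 0.00572 to 0.754 over the alternatives). Of 16 genes of the glyoxylate cycle and gluconeogenesis, 4 were lower and 1 higher, also over the list alone. CAT2 differed by -0.70, IDP2 by -0.67, FBP1 by -0.61 and MDH2 by 0.35 (list median -0.30, camera adjusted p = 0.641). In peroxisomal beta-oxidation 6 of 17 genes were lower and 1 higher, also over the list alone. The catalase gene CTA1 differed by -0.80, PXA1 by -0.68, SPS19 by -0.57 and FOX2 by -0.45 (list median -0.23, camera adjusted p = 0.638). In ergosterol synthesis 3 of 25 genes were higher and 3 lower (1 and 2 over the list alone). ERG9 was higher by 0.24, and ERG8, ERG27 and ERG24 were lower at -0.39, -0.31 and -0.24. That median was 0.01, against a mean of -0.01, and turned negative after quantile normalization (camera adjusted p = 0.143). With arrays centred on the brighter probe sets the list passed as higher, at 0.11 (adjusted p = 0.0486, within a range of 0.0486 to 0.517). The 2 lower hexose transport genes fell to 0 without flo8Δ array 1, 2 or 4, without either mss11Δ array and with either centring, and to 1 without flo8Δ array 3. The 2 higher ones fell to 1 without flo8Δ array 1, 2 or 4 or mss11Δ array 2. The 6 lower genes of beta-oxidation fell to 3 without flo8Δ array 2 or either mss11Δ array. The 4 of the glyoxylate cycle fell to 1 without either mss11Δ array and rose to 8 without flo8Δ array 3. Of the 3 higher and 3 lower ergosterol genes, 1 and 1 were left without either mss11Δ array, 1 and 2 without flo8Δ array 1 or 2, and 0 and 2 without flo8Δ array 4.

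Genes that mark haploid cells or the meiotic state were lower in flo8Δ where they passed, with few exceptions. Lower calls also prevailed over all genes, with 1781 of 5656 lower and 619 higher at 1 probe set per gene. Of the lists in this paragraph only meiosis and sporulation passed camera in the main fit. In the a-specific list 5 of 7 genes were lower, also over the list alone, with the pheromone genes MFA1 at -1.13 (-0.40 in another probe set, which did not pass) and MFA2 at -0.74, ASG7 at -0.62 and AGA2 at -0.29 (median -0.36, camera adjusted p = 0.0768). That list passed without flo8Δ array 1 (adjusted p = 0.0270) and with either centring (adjusted p = 0.0476 and 0.0345), within a range of 0.0270 to 0.297. Of 4 alpha-specific genes, SAG1 was lower at -0.67 and STE3 at -0.55, with the same counts over the list alone (median -0.28, camera adjusted p = 0.638). Of 11 haploid-specific genes, 4 were lower and 1 higher, and 8 and 1 over the list alone. FAR1 differed by -0.72, AXL1 by -0.71, STE4 by -0.67 and STE5 by -0.50, and the higher one was the kinase gene FUS3, in a probe set below background in mss11Δ (median -0.15, camera adjusted p = 0.222). Of 13 pheromone-induced genes, 2 were higher and 3 lower (1 and 3 over the list alone). PRM5 was higher by 0.91, and KAR5, FIG1 and PRM3 were lower at -0.62, -0.54 and -0.17. The pheromone list's median was -0.11, against a higher direction in camera (adjusted p = 0.949). In meiosis and sporulation 16 of 38 genes were lower and 1 higher (19 and 1 over the list alone). REC102, a recombination gene, differed by -1.18, SPO1 by -1.01 and SPS4 by -1.00. SMK1, below background in flo8Δ, was at least 1.29-fold lower, while IME1, the activator of meiosis, was higher by 0.38. That median was -0.21 (camera adjusted p = 0.0308, and adjusted p = 0.631 with an estimated correlation), and without mss11Δ array 2 it was -0.15 (adjusted p = 0.0626). The 16 lower genes of meiosis fell to 9 without flo8Δ array 2, 10 without flo8Δ array 4, 5 without mss11Δ array 2 and 6 with arrays centred on the brighter probe sets, and rose to 29 after quantile normalization. The 5 lower a-specific genes fell to 3 without mss11Δ array 1 or flo8Δ array 2 or 4, and to 2 without mss11Δ array 2. Without mss11Δ array 2, 1 alpha-specific, 2 haploid-specific and 1 pheromone-induced gene were lower, and after quantile normalization 4, 8 and 8. The ACT1 control difference of -0.48 against -3.71 went with these groups as well.

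At the G1/S transition 15 of 24 genes were lower and 1 higher (16 and 1 over the list alone). CLN1, a cyclin, differed by -0.65, RFA2, a subunit of replication protein A, by -0.54 and POL1, a DNA polymerase subunit, by -0.48. The S-phase cyclin gene CLB6 was the higher one, at 1.26. The G1/S median was -0.41 (camera adjusted p = 0.0358, and adjusted p = 0.575 with an estimated correlation). It missed the threshold without flo8Δ array 3, at -0.38 (adjusted p = 0.0564), and without mss11Δ array 2, at -0.37 (adjusted p = 0.108). Of 15 G2/M genes, 8 were lower (9 over the list alone) and none higher. KIN3 differed by -0.92, ALK1 by -0.74, CLB4 by -0.57 and HOF1 by -0.37 (median -0.37, camera adjusted p = 0.0503). The G2/M list passed in 5 refits, among them without flo8Δ array 2 (adjusted p = 0.0157) or 4 (adjusted p = 0.0360), within a range of 0.0157 to 0.164. The lower genes of the G1/S list fell to 9 without mss11Δ array 1 and to 5 without array 2, and those of the G2/M list to 4 and 5. With arrays centred on the brighter probe sets 10 and 5 were lower. For daughter cell separation SUN4 and EGT2 were higher by 0.56 and 0.55 and DSE1 was lower at -0.50, of 9 genes and with the same counts over the list alone (median 0.01, camera adjusted p = 0.160). None of 3 measured histone genes passed, also over the list alone, with HTB1 at -0.18, HTZ1 at -0.14 and HTB2 at -0.11 (median -0.14, camera adjusted p = 0.706). These values too were measured across the ACT1 control shift from -0.48 to -3.71.

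At the cell surface, 7 of 25 cell wall genes were higher in flo8Δ and 4 lower, and 9 and 5 over the list alone. PIR1 was higher by 0.49, SED1 by 0.43 and CCW14 by 0.33, and the glucan-remodelling gene GAS3 was lower at -0.65. The cell wall median was 0.07 (camera adjusted p = 0.0271, and adjusted p = 0.296 with an estimated correlation). Of 6 anaerobic mannoprotein genes, TIR4 and TIR2 were higher, by 0.67 and 0.58, also over the list alone. That median was 0.26 (camera adjusted p = 0.0271, and adjusted p = 0.522 with an estimated correlation). After quantile normalization both lists missed the threshold (adjusted p = 0.0794 for each), and the anaerobic list also without mss11Δ array 1 (adjusted p = 0.0576), within ranges of 0.0221 to 0.125 and 0.0146 to 0.10 over the alternatives. Of 10 seripauperin genes, near-identical subtelomeric copies whose signals cannot be kept apart, 5 were lower, also over the list alone, with PAU17 at -0.47, PAU7 at -0.36, PAU19 at -0.32 and PAU3 at -0.25 (median -0.25, camera adjusted p = 0.145). Of 8 COS genes, another near-identical family, 3 were higher and 1 lower, also over the list alone. COS10 was higher by 4.74, COS7 by 2.25 and COS6 by 0.48, and COS12 was lower at -0.56 (median 0.02, mean 0.79, camera adjusted p = 0.0638). The COS list passed in 3 refits, among them without flo8Δ array 2 (adjusted p = 0.0447) and without mss11Δ array 1 (adjusted p = 0.0196), within a range of 0.0196 to 0.461, and its median lay under 0 without flo8Δ array 3 or mss11Δ array 2. No Y prime helicase gene was measured. Of the cell wall genes, 3 were higher and 3 lower without mss11Δ array 1, 3 and 1 without mss11Δ array 2, 5 and 2 without flo8Δ array 4, and 12 and 1 with arrays centred on the brighter probe sets. The lower seripauperins fell to 2 without mss11Δ array 1 and to 1 without mss11Δ array 2, and the higher anaerobic genes to 1 without either.

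Among nutrient regulons, iron uptake genes had 4 of 17 members higher and 1 lower, also over the list alone. FIT1, SIT1 and FIT3, of siderophore-bound iron uptake, were higher by 0.58, 0.53 and 0.48, and the reductase gene FRE1 was lower at -0.35. The iron median was 0.07 (camera adjusted p = 0.0166, and adjusted p = 0.321 with an estimated correlation). In the phosphate list, PHO89 was higher by 2.00 and PHO81 by 0.26, and PHO84 and VTC2 were lower at -0.73 and -0.35, of 13 genes and with the same counts over the list alone. Camera placed the phosphate list higher, and its mean was 0.0009, against a median of -0.10, which turned positive with arrays centred on the brighter probe sets (adjusted p = 0.845). Of 8 zinc genes, ZRT1 was higher by 0.43 and ZRT3 lower at -0.33, also over the list alone (median -0.12, higher in camera, adjusted p = 0.845). Of 11 genes of thiamine and pyridoxine synthesis, some of them near-identical, 2 were higher and 4 lower, also over the list alone. SNO1 and SNZ1, of vitamin B6 synthesis, were higher by 1.32 and 1.22, and PHO3 and THI6 were lower at -0.59 and -0.38 (median -0.18, mean 0.004, higher in camera, adjusted p = 0.957). Of the iron genes, 2 were higher and 0 lower without mss11Δ array 1, and 1 and 1 without mss11Δ array 2. In the phosphate list 1 gene was higher and 1 lower without either mss11Δ array, and the lower genes of thiamine and pyridoxine synthesis fell to 2.

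Of 81 genes matched as ribosomal proteins, 2 were higher and 2 lower, and none over the list alone. RPP2A and RPL7A were higher by 0.75 and 0.68, RPS22B was lower at -0.56, and the other lower one, RPP1 at -0.38, encodes a subunit of ribonuclease P and was matched by its name. The ribosomal protein median was -0.06, against a higher direction in camera, and turned positive with arrays centred on the brighter probe sets (adjusted p = 0.0948). The list passed camera as higher in 6 of 17 refits, with a positive median in each, within a range of 2.60e-06 to 0.558 over the alternatives. Among them it was 0.03 without flo8Δ array 3 (adjusted p = 8.23e-05), 0.002 without mss11Δ array 2 (adjusted p = 0.0441) and 0.08 without both (adjusted p = 2.60e-06). With an estimated correlation its adjusted p was 0.915 with all arrays and 0.669, 0.913 and 0.752 in these refits. Without flo8Δ array 3, 12 ribosomal protein genes were higher and 3 lower. RPL7A had other probe sets at 0.64 and 0.54 that did not pass. In ribosome biogenesis 23 of 52 genes were lower and 2 higher (23 and 4 over the list alone), with UTP20 at -0.66, UTP21 at -0.59, IMP4 at -0.57 and DIP2 at -0.54 (median -0.23, camera adjusted p = 0.115). UTP20 went the other way in 4 of its other probe sets, 1 higher by 2.09 and the others by at least 2.42-fold, 2.43-fold and 3.23-fold. The 23 lower genes fell to 15 without flo8Δ array 2 or 4, to 11 without mss11Δ array 1, to 8 without mss11Δ array 2 and to 12 with arrays centred on the brighter probe sets. Of 32 stress response genes, 4 were higher and 5 lower (1 and 2 over the list alone), with GPH1 at -1.44, ALD3 at -0.52, SOD2 at 0.33 and CTT1 at 0.31 (median -0.11, higher in camera, adjusted p = 0.355). Of 16 chaperone genes, 3 were higher and 3 lower, also over the list alone. HSP10 was higher by 0.76, SSA1 by 0.68 and SSA2 by 0.43, and SSA3 was lower at -0.27. The chaperone median was -0.06, against a mean of 0.01 and a higher direction in camera, and turned positive with arrays centred on the brighter probe sets (adjusted p = 0.501). Of 32 proteasome genes, 2 were higher and 6 lower (0 and 1 over the list alone), with PRE10 and PRE3 at -0.32 (PRE3 at -0.33 and -0.03 in probe sets that did not pass), RPT4 at -0.30 and PUP3 at 0.24. The proteasome median was -0.10, against a higher direction in camera, and turned positive with arrays centred on the brighter probe sets (adjusted p = 0.846). Of 7 marker genes used to build laboratory strains, ADE2 was higher by 1.03, LYS2 by 0.36 and URA3 by 0.27, also over the list alone, while CAN1 at 0.32, HIS3 at 0.30, TRP1 at -0.16 and LEU2 at -0.01 were not past the threshold. The marker median was 0.30 (camera adjusted p = 0.0120, and adjusted p = 0.296 with an estimated correlation). LEU2 had other probe sets that were higher by 1.37 and 2.09. Without mss11Δ array 2 the higher and lower genes numbered 0 and 2 in the stress list, 2 and 0 among chaperones, 4 and 1 in the proteasome and 1 and 0 among markers. Without mss11Δ array 1 they numbered 2 and 2, 2 and 0, 0 and 2, and 2 and 0.

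In all, 12 of 38 tested lists passed camera with a preset correlation, 9 placed higher and 3 lower. Camera compares a list with the other genes, and the median difference over all genes was -0.14. A list placed higher may thus have a median near 0. Such medians were 0.02 for the respiratory chain, 0.03 for filamentous growth regulators, and 0.07 for both the iron and the cell wall genes. None of the lists passed with an estimated correlation, in this fit or in any of the 17 refits. Each list was compared across the same shift of the ACT1 control, -0.48 against -3.71, and with that control as a covariate 3 lists passed: sulfate and methionine, glycolysis and fermentation, and the respiratory chain. Fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 23 lists. It passed sulfate and methionine (adjusted p = 0.00516) and, among lists that camera did not pass, ribosome biogenesis (adjusted p = 0.00488) and the seripauperins (adjusted p = 0.00516).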

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

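Tests chosen only after the result was seen were those on genes with several probe sets, on gene length, on rRNA on flo8Δ arrays 1, 2 and 4, on genes with 1 probe set on flo8Δ array 3, on the sulfur list against matched genes, on array 3 and with the ACT1 covariate, on the G1/S list, and on mixed RNA; centring on the brighter probe sets was also added late.

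flo8Δ array 3 stood apart from the other flo8Δ arrays in 7 of the 8 groups of 4 arrays in which 1 array lay far from the rest, out of 54 groups tested. Chance marks about 1 in 20 groups. The gap to the nearest array, as a share of the whole range, was 0.967 for GSC2 (10.64 on array 3, 11.37 on average on the others), 0.844 for VMA1 (10.03, 10.66), 0.949 for ERG12 (9.55, 10.04) and 0.889 for GPH1 (8.64, 7.95). It was 0.920 for TRP1 (10.77, 10.50), 0.932 for the SRB4 5′ minus 3′ control (-2.39, -1.57) and 0.833 for the median of the G1/S list (8.58, 8.77). The eighth, on flo8Δ array 1, was the median of the TCA cycle list, at 0.973 (10.95, 10.88).

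In 6 of these 7 groups array 3 lay toward the mss11Δ level, while the G1/S list lay away from it (8.86 and 9.05 in mss11Δ). RNA of mss11Δ mixed into that sample is argued against by FLO8, which differed from the other flo8Δ arrays by -0.0089 (their SD 0.0420) and read 3.31. Across probe sets the array 3 deviation had a slope of 0.247 on the mss11Δ minus flo8Δ difference. Taken as a mixing share, that slope would give 6.39 for FLO8. This is only a rough figure, because the slope was fitted on log2 values. Within 137 genes the 2-fold higher probe set with the largest difference deviated by a median of -0.64 relative to the brightest other one. A smaller loss of 5′ signal on that array may therefore account for part of the shift. It is open as an account of the whole shift: the 486 higher probe sets deviated by -0.53, and the 32 lower ones by 0.43 where such a loss predicts little. A culture in a state between the groups predicted that last shift, seen in 30 of the 32, and remains open for them, but is argued against for the G1/S list, which deviated by -0.17 (7 of 24 genes upward) where it predicts a rise.

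The excess of 2-fold higher probe sets, 486 against 32, went with the loss of 5′ signal on the mss11Δ arrays, where the ACT1 control difference reached -4.97 on array 2 against -0.48 on average in flo8Δ. Carried-over rRNA on flo8Δ arrays is argued against for these probe sets as a set. Their median level was only 0.026 higher on array 4 than on array 1. The 25S rRNA control read 7.98 and 5.82 on those arrays and 5.67 on mss11Δ array 2. The -0.53 on array 3 does not decide this alone, since array 3 may have lost 5′ signal itself. Carry-over remains open for single rRNA genes. On array 3 RDN25-1 deviated by 2.75 and 1.19, RDN5-1 by 0.89 and 1.17, and RDN37-1 by -0.44 and 0.08. Long genes are argued against for genes with 1 probe set. Of these, the 164 with a 2-fold higher value had a median length of 709.5 (other genes 1242). For 137 genes with several probe sets the median was 3192 (others 955.5), which cannot decide whether length plays a part. A gene entered there through any of its probe sets, and the number of probe sets was not matched. The long genes FAS1, FAS2 and FKS1 had 8 each. In the 137 genes with several probe sets, the 2-fold higher one with the largest difference had a median of 3.36. With probe sets below background in mss11Δ at their bound it was 3.19. The other probe set brightest over all 6 arrays had a median of -0.10, as a loss of 5′ signal may produce. These choices may widen the contrast, because brightness over all arrays favours probe sets that kept signal in mss11Δ. Its size therefore does not measure the loss. For genes with 1 probe set the evidence is mixed. On mss11Δ array 2 they lay below array 1 in 51.7% of 118 genes (other genes 46.5%), which decides nothing. On flo8Δ array 3 such genes deviated by a median of -0.27 (n = 164, other probe sets 0.04). YOR302W, also with 1 probe set, differed by 5.97 while CPA1, whose mRNA has it in its 5′ leader, differed by 0.005, as a loss of 5′ signal may produce. RNA integrity follows genotype in these 6 arrays, so an effect of MSS11 on single genes remains open as well.

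For the lower level of sulfate and methionine genes in flo8Δ, compensation by the normalization for signal lost elsewhere is argued against, since the list lay at -0.59 relative to brightness-matched genes. A single array is argued against by a list median that stayed between -0.63 and -0.73 without each array in turn, although the count of lower genes fell from 17 to 10 without mss11Δ array 1 and to 8 without array 2. A state of the culture or RNA that goes with integrity rather than genotype cannot be told apart from it, because the list on flo8Δ array 3 lay above the other flo8Δ arrays by 0.14 (16 of 21 genes), between what either account predicts. With the ACT1 control as a covariate the list mean was -0.80 ± 0.30 (SE; -0.74 ± 0.11 without it), so it did not shrink, but its 95% interval of -1.77 to 0.17 leaves such a trend open too. A difference between the genotypes therefore may underlie it but stays a hypothesis.

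Among 2443 probe sets without a listed gene, 91 differed by at least 2-fold, 70 higher and 21 lower in flo8Δ. Centring on the brighter probe sets took the count of lower calls from 1777 to 900, a drop of 49.4%, which leaves open how many of the small lower calls come from the scaling. The 15 splits of the 6 arrays into 4 and 2 are too few for a share under 0.05; the real split called 2760 probe sets and the highest other split 0.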

How the results depend on the processing

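Centring on the brighter probe sets, the background filter, the ACT1 covariate, leaving out flo8Δ array 3 with mss11Δ array 2, and the mean of all probe sets were tried only after the data were seen. FLO8 and MSS11 kept their direction and stayed past the threshold under every alternative that tested them; the filter on dim probe sets removed them and FLO11. Leaving out each array in turn gave 1274 to 3135 calls (610 to 1102 higher, 664 to 2033 lower), FLO8 from -4.93 to -4.88, MSS11 from 3.04 to 3.60, FLO11 from -0.24 to -0.14, and 11 to 14 lists. The count was 1580 (861 lower) without mss11Δ array 1, 1274 without mss11Δ array 2, and 1827 without flo8Δ array 4, with 1069 lower without flo8Δ array 2 or 4; where 1 mss11Δ array was left, it was assumed to vary like the flo8Δ arrays. Without the dim probe sets 4554 were tested and 1762 called (480 higher, 1282 lower). Higher calls made up 27.2% of these, against 35.6% in the main fit. By at least 2-fold 112 were higher and 20 lower, against 486 and 32 in the main fit. The smaller number of tests alone therefore does not account for the fall in higher calls. At 2-fold the count was 518 (486 higher, 32 lower), SAM gave 348 (201 and 147), and 1 probe set per gene gave 619 higher. Centring on the brighter probe sets gave 900 lower and 1207 higher (57.3%). The ACT1 covariate gave 88 (79 higher, 9 lower, 89.8% higher) and 3 lists. MET32 went from -2.00 (SE 0.24) to -2.32 (SE 0.59), so its call ended with a wider error. Other differences shrank, among them TEF4 from 6.02 to 3.88 and FAS1 from 6.55 to 5.39. The ACT1 control itself separates the genotypes, so the 88 are not a count of differences free of RNA integrity. Without flo8Δ array 3 and mss11Δ array 2, 2089 were called (898 and 1191) and 8 lists. FLO11 passed at -0.45 after quantile normalization; the cause was not tested. Estimated correlation left 0 lists and fry passed 23. Where a call was involved, the sign turned for MF(ALPHA)2, from 0.03 to -0.34 after quantile normalization, and for amino acid biosynthesis, to -0.14 with the covariate. Without a call in either fit, 8 named genes changed sign, 23 times in all. Some other list medians also changed sign, as given with those lists. The causes were not tested. Sulfate and methionine (medians -0.73 to -0.58), glycolysis and the respiratory chain passed in all 17 refits, while meiosis passed in 11 and G1/S in 10. Of 2875 values of named genes other than FLO8, MSS11 and FLO11, 446 lost the threshold (142 with the covariate) and 13 gained it. The 286 probe sets below background on all arrays carry no usable signal.

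With the replicate number as a replicate block 1660 were called, 883 lower and 777 higher (46.8%). The numbers do not pair the arrays: only 2 are shared, and deviations of arrays with the same number correlated at 0.0478 and -0.148.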

Other observations

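All genes in this paragraph except CLN1, a member of lists fixed beforehand, were chosen after their values were seen. No further tests were run on any of them. Of 12 genes of sulfur metabolism outside the list fixed beforehand, 5 were lower in flo8Δ, 2 were higher, 4 were not past the threshold and 1 had probe sets in both directions. MET4, the activator of the sulfur genes, differed by -0.66 (adjusted p = 0.00364) and MET30, which restrains it, by -0.68 (adjusted p = 0.00994). MHT1, which recycles S-methylmethionine, differed by -1.29, MUP3, a methionine permease, by -0.89, and DUG2, of glutathione breakdown, by -0.95. JLP1, which releases sulfite from sulfonates, went the other way, higher by 2.07 (adjusted p = 0.000983), as did CBF1, a factor that binds sulfur gene promoters, by 0.85 (adjusted p = 0.0142). MET31 at -0.21, MET22 at -0.30, MET13 at -0.17 and DUG1 at -0.05 were not past the threshold. SAM3, an S-adenosylmethionine permease, had 2 lower probe sets, at -1.04 and -1.16, and 3 higher ones, at 3.49, 3.05 and 3.54, the first of uncertain size because 1 mss11Δ array lay below background. The G1 cyclin gene CLN3 was higher in flo8Δ by 1.63 (adjusted p = 0.000675), while the later G1 cyclin gene CLN1 was lower at -0.65.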
